A study of Mus musculus with 12 samples.

How the data were processed

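RNA-seq gene counts were available for 12 mouse small-intestine libraries in 4 groups of 3. Per the labels' protocols, embryonic epithelial cells were sorted as EpCAM-positive, CD31-negative and CD45-negative. Adult stem cells were sorted from crypts by high Lgr5-EGFP fluorescence, and adult villus epithelium was sorted by the same 3 surface markers as the embryonic cells. RNA came from a pool of 20 embryos per E12.5 library and from 1 gut per adult library, with the E14.5 pool size not given in the sources used here. Per the labels' protocols, 50 ng of total RNA was amplified to cDNA with an Ovation kit, and the sheared cDNA was made into libraries with a NEBNext kit.

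The deposited values are raw counts of reads per gene symbol, 1 file per library, not normalised by the authors. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.3.1z13, SAMtools 1.2, HTSeq 0.6.1p1, DESeq2 1.6.3 and the mm9 build. Their roles, the gene annotation and the strand setting are not given in the sources used here, so overlapping and antisense genes could not be told apart. Each file holds 23366 gene entries and 5 closing counts that name no gene, which stayed out of library sizes and tests. Reads listed outside annotated genes made up 33.4% to 58.1% of all reads listed. Reads listed as not uniquely aligned made up 3.06% to 5.96% of the E12.5 and ISC libraries and were listed at 0 in all 6 E14.5 and AE libraries, and ambiguous reads made up 0.531% to 1.00%. No coordinates are given here, because the reference at hand was a later build than mm9. Its transcripts served only to measure shared sequence.

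Groups and replicate numbers were taken from the sample titles. In all 6 embryonic libraries the age label gives the other stage than the title, so the sign of the E14.5 against E12.5 comparison rests on the titles. Every pair of replicates differed by more than sampling noise, from a chi-square per degree of freedom of 3.49 for E14.5 replicates 1 and 2 to 173 for AE replicates 1 and 2, and all 12 libraries were kept.

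Counts were tested with edgeR 4.0.16 under R 4.3.3, by quasi-likelihood F tests on all 12 libraries with 1 coefficient per group and no covariate. Genes were kept by the edgeR expression filter, leaving 15342. Library sizes were scaled by trimmed mean of M values (TMM), with factors from 0.696 to 1.16. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The common biological coefficient of variation was 0.154. Levels are TMM-normalised counts per 1000000 (CPM), given as mean ± SD of 3 libraries. Fold changes come from the fit, with a prior count of 0.125. Where all 3 libraries of a group held 0 counts, a bound is given against a floor of 3 counts over the group, equal to 0.0371 CPM in E12.5, 0.0263 in E14.5, 0.0525 in ISC and 0.0606 in AE. Where a group held 1 to 3 counts, levels and counts are given without a fold. Floors cover counting error only, since amplified reads are not independent molecules.

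Before the data were examined, 40 gene lists with 1125 entries were fixed, of which 1105 matched a gene symbol. They cover stem-cell, signalling, cell-cycle, absorptive, secretory, chromatin, immune, metabolic and stress genes, and markers of mesenchyme, endothelium, immune cells, enteric neurons, red cells and neighbouring organs. Each list was tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 40 lists of a comparison, and again with an estimated correlation. The estimate came from the spread within groups over all 12 libraries, so every comparison used libraries outside it as well. Members past the threshold were counted over all genes tested and adjusted over the list alone. The genes to name were also fixed by rule. The rule took the 5 largest changes each way among genes of at least 20 CPM in the higher group with no overlap between libraries. It also took up to 2 members of each list described, of at least 5 CPM in the higher group, and Lgr5, Olfm4, Mki67, Cdx2, Hnf4a and Epcam in every comparison. For genes enriched in 1 group it took the 4 with the largest smallest change, and markers of other cell types above 50 CPM could be named with their levels. Some genes covered by the rule are not reported here.

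Shared sequence was measured as the share of a gene's 50-base stretches found in transcripts of another gene on either strand. Transcripts of other genes that overlap at the same locus count as sharing too. A shared stretch therefore does not show that its reads align in several places. Of the gene entries, 23005 had a sequence and 13513 shared at least 1 stretch. Of 211 genes covered by the naming rule, 26 shared over 20% and 2 had no sequence. Members of the alpha-defensin, histone, H2-Q and other near-identical families are uncertain for the same reason.

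The tests were run on simulated counts with a seeded set of changed genes, drawn at the depth of the real libraries. Each gene had 1 mean and 1 spread over all 12 libraries, and genes were drawn independently. For E14.5 against E12.5, over 14892 simulated genes, edgeR recovered 22.7% of 1.5-fold, 68.7% of 2-fold and 93.8% of 4-fold changes, with 7.1% of calls false. For ISC against E14.5 over 14899 genes it recovered 23.9%, 70.1% and 93.8%, with 5.1% false. For AE against ISC over 14858 genes it recovered 23.1%, 58.2% and 91.9%, with 1.6% false. In the same order, 22.2%, 15.1% and 9.6% of DESeq2's calls were false and 10.7%, 5.9% and 0% of limma-voom's. The simulations held far fewer changed genes than the real comparisons called, with 140, 136 and 122 edgeR calls in the same order. That makes the adjusted threshold stricter there, so these shares do not carry over to the real calls. The simulated spread was also equal in all groups. In highly counted genes, real replicates differed by a log2 SD of 0.046 (E14.5 replicates 1 and 2) to 0.36 (AE replicates 1 and 2).

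The alternatives were DESeq2 1.42.0, relative log and upper-quartile scaling, no filter on low counts, at least 1 CPM in 3 libraries, limma-voom, the 6 compared libraries alone, the replicate number as a block, leaving out each library, and the estimated correlation for lists. The list tests were run under these except DESeq2 and limma-voom. Chosen after the data were seen were a run on genes that share no 50-base stretch with another gene and a run without Rn45s and Lars2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 handled tables and figures.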

Results

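Gene expression was measured by RNA-seq in mouse small-intestinal epithelium along a course from the embryo to the adult villus, with 3 biological replicates in each of 4 groups. E12.5 and E14.5 were embryonic epithelial cells, named by embryonic day and sorted for the epithelial surface protein EpCAM and against CD31 and CD45, which mark endothelium and white blood cells. ISC were adult stem cells with high Lgr5-EGFP fluorescence, Lgr5 being a receptor that marks crypt base stem cells, and AE were villus epithelial cells that the labels call enterocytes. Both adult groups came from males at postnatal day 60. In all 6 embryonic libraries the age label gives the other stage than the title, and the titles were followed here. Total gene counts, in units of 1000000, averaged 24.1 ± 4.25 (SD, n = 3) in E12.5, 33.2 ± 12.9 in E14.5, 18.2 ± 3.84 in ISC and 21.4 ± 11.3 in AE, with single libraries between 12.6 and 45.2. Levels are mean ± SD of 3 libraries in normalised counts per 1000000 (CPM), and gene calls have adjusted p under 0.05 by edgeR's quasi-likelihood test.

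The libraries split by group in how multiply aligned reads were listed, and the sources used here give no reason. Reads with more than 1 alignment were listed in E12.5, at 1.99 ± 0.369 per library in units of 1000000, and in ISC, at 2.14 ± 0.212, but at 0 in each E14.5 and AE library. Each of the 3 comparisons along the course crosses this split, so a batch that follows it and the group cannot be told apart there. In fits of the 6030 genes sharing no 50-base stretch with another gene, chosen after the data were seen, 3096, 3767 and 3973 genes passed, of which 3064, 3733 and 3832 were called in the same direction over all genes. ISC against E12.5 and AE against E14.5 lie within it, with 10513 and 12000 genes past the threshold.

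**Figure D1:**
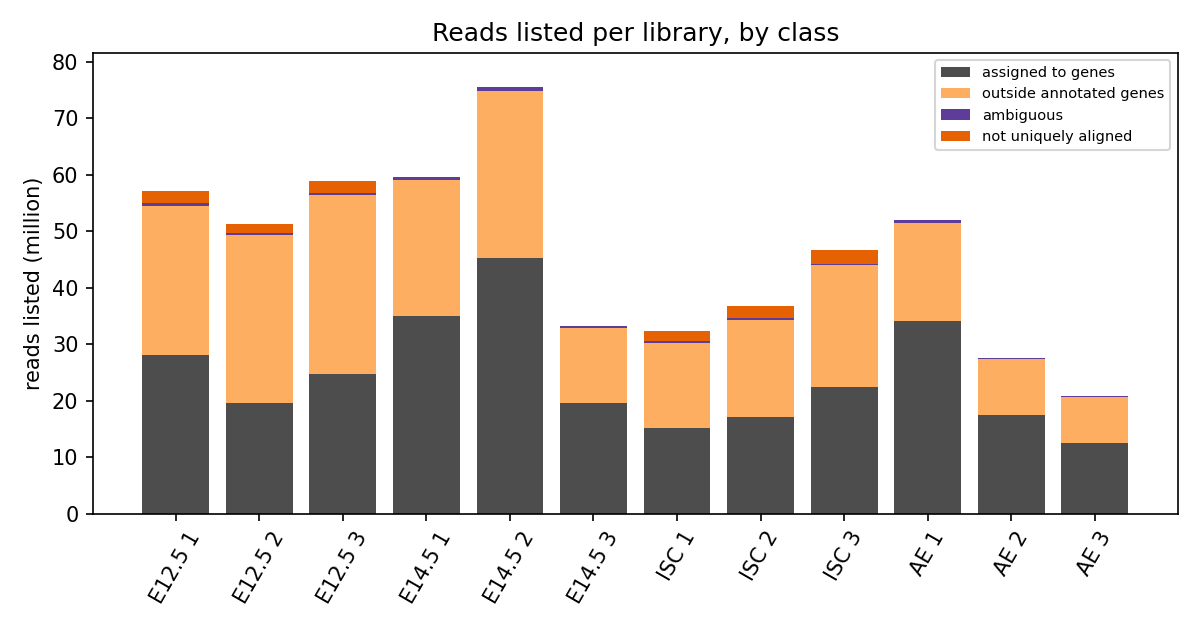
Reads listed per library in units of 1000000, stacked by class, for 3 libraries of each of the 4 groups. Reads not uniquely aligned appear in the E12.5 and ISC bars and are listed at 0 in the E14.5 and AE bars.

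The 4 populations were far apart. Of 15342 genes tested, 14318 (93.3%) differed between at least 1 pair of groups, and the first principal component, with 74.5% of the variance, ran from E12.5 through E14.5 and ISC to AE. The second, with 16.3%, set ISC apart from the rest. By the criterion of a log2 change of at least 1 over each other group, 1389 genes were enriched in E12.5, 238 in E14.5, 485 in ISC and 2136 in AE. E12.5 was led by P4ha3 at 124 ± 11.5 CPM, which encodes a collagen prolyl hydroxylase subunit, and by 2610307P16Rik, the atypical cadherin gene Fat3 and the potassium channel gene Kcnq3. E14.5 was led by Ctrb1, a pancreatic chymotrypsinogen gene, at 70.0 ± 51.0 CPM, and by the smooth-muscle genes Actg2, Myh11 and Acta2, at 31.6 ± 4.75, 61.5 ± 11.1 and 65.7 ± 10.1 CPM. Ctrb1 stood at 49.9, 32.2 and 128 CPM in E14.5 replicates 1, 2 and 3, so its level and rank lean on replicate 3. ISC was led by 4933417O13Rik at 82.0 ± 6.46 CPM, the glutamate transporter gene Slc1a2 at 118 ± 40.6 CPM, A930009A15Rik and Cyp2e1. AE was led by Tmprss15, encoding enteropeptidase, 2010109I03Rik, the intestinal alkaline phosphatase gene Akp3 at 1614 ± 705 CPM, and Ido1, a tryptophan-degrading enzyme gene, at 160.3 ± 13 CPM.

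**Figure D2:**
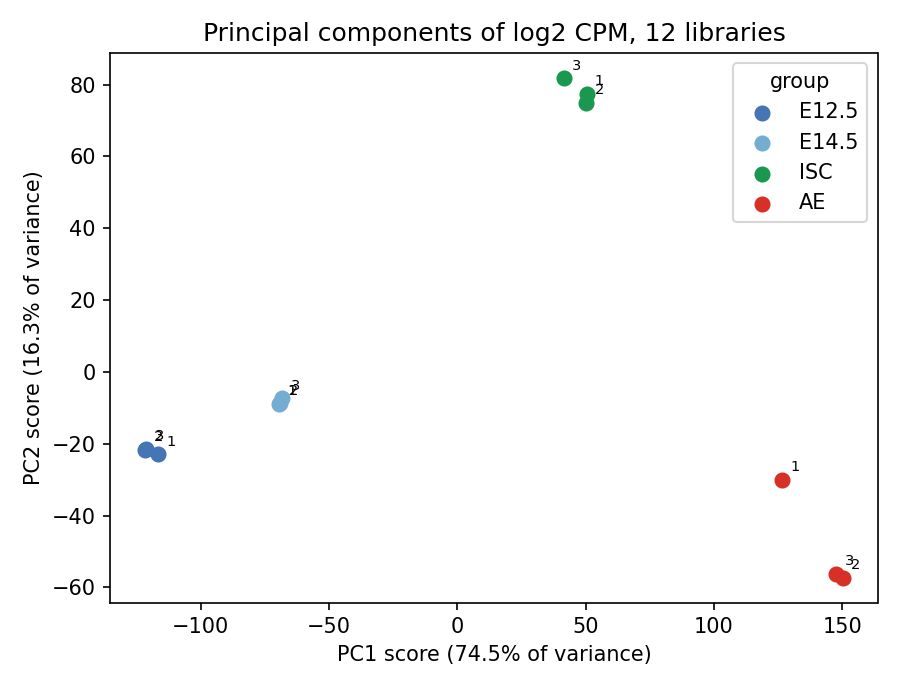
Scores of the 12 libraries on the first 2 principal components of log2 CPM, with the replicate number beside each point and each axis labelled with its share of variance, 74.5% and 16.3%. The groups are separate, and AE replicate 1, at 127 and -30.0, lies apart from AE replicates 2 and 3, at 150 and -57.3 and at 148 and -56.1.

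The comparison of E14.5 with E12.5 asked how the embryonic epithelium changed over the days on which villi begin to form. The lists called higher at E14.5 included microvillus, lipid absorption, goblet-cell and oxidative phosphorylation genes, and those called lower included oncofetal and imprinted genes. None of the 17 list calls held with an estimated correlation, where the lowest adjusted p was 0.0693. That correlation was estimated over all 12 libraries, adult ones included, so these losses do not show co-variation among the embryonic libraries alone. Cdx1, a homeobox gene of intestinal identity, rose from 0.866 ± 0.114 to 23.1 ± 0.222 CPM, and Dmbt1, encoding a mucosal scavenger glycoprotein, rose 66.6-fold from 6.54 ± 7.53 to 446 ± 15.9 CPM, or 202-fold without E12.5 replicate 1. Hnf4a, a transcription factor gene of digestive epithelium, rose 3.41-fold to 1027 ± 23 CPM, and the stem-cell receptor gene Lgr5 rose 3.30-fold to 81.8 ± 3.69 CPM. The lists holding Cdx1 and Hnf4a and holding Lgr5 were not called, with 14 of 38 intestinal transcription factor genes up and 14 down (adjusted p = 0.643) and 13 of 29 stem-cell genes up and 10 down (adjusted p = 0.149). Olfm4 stood at 2.38 ± 0.282 and 1.49 ± 1.29 CPM (adjusted p = 0.147, and 0.0489 with limma-voom and 7.91e-05 without E12.5 replicate 3), and Epcam rose 1.77-fold. Shh, encoding the ligand by which epithelium signals to mesenchyme and uncertain because 23.6% of its sequence is shared with other genes, fell 2.93-fold, from 564 ± 14.9 to 192 ± 9.92 CPM.

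In the absorptive lists, 18 of 26 microvillus genes rose and 2 fell (camera adjusted p = 2.28e-05, and adjusted p = 0.418 with an estimated correlation). Eps8l3, an actin regulator gene that shares 27.8% of its sequence and is uncertain, rose from 2.09 ± 2.16 to 137 ± 3.67 CPM, and Myo1a, the brush-border myosin gene, rose 15.3-fold. Of 34 lipid absorption genes, 21 rose and 2 fell (adjusted p = 0.000416, and adjusted p = 0.656 with an estimated correlation). They included Fabp1, a fatty acid-binding protein gene, at 7.09-fold, and Apoa4, an apolipoprotein gene, at 6.79-fold. Apoa4, which shares 60.9% of its sequence and is uncertain, missed the threshold with limma-voom, at adjusted p = 0.0912. Of 37 xenobiotic metabolism genes, 21 rose and 1 fell (adjusted p = 0.000944, and adjusted p = 0.656 with an estimated correlation). The organic anion pump gene Abcc2 rose 13-fold and Cyp2c55 rose 10.6-fold. Brush-border hydrolases (12 of 22 up, 2 down, adjusted p = 0.0832) and nutrient transporters (12 of 37 up, 3 down, adjusted p = 0.0848) missed the list threshold. Both passed it without the filter on low counts (adjusted p = 0.0433 and 0.0404) and in a fit of the 6 libraries alone (adjusted p = 0.0369 and 0.0411). The phosphatase gene Alpi rose 12-fold and the glucose transporter gene Slc5a1 rose 4.02-fold. E12.5 replicate 1 was the highest E12.5 library for Eps8l3, Myo1a, Cyp2c55 and Alpi, and without it the rises were 164-, 24.7-, 19.2- and 18.1-fold.

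Of the secretory lists, that of goblet cells was called. Of 19 goblet-cell genes, 16 rose and 0 fell (adjusted p = 6.87e-07, and adjusted p = 0.382 with an estimated correlation). Atoh1, the transcription factor gene of the secretory fate, went from 4 counts over the E12.5 libraries to 6.12 ± 0.770 CPM. Epithelial defence genes rose in 15 of 30 and fell in 1 (adjusted p = 0.00153, and adjusted p = 0.418 with an estimated correlation), with Lypd8, encoding a mucosal barrier protein, at 926 ± 56.9 against 102 ± 40.2 CPM. Antigen presentation genes rose in 14 of 27 and fell in 1 (adjusted p = 0.00498, and adjusted p = 0.656 with an estimated correlation), with H2-K1 at 4.37-fold. The enteroendocrine list had 12 of 27 up and 3 down (adjusted p = 0.0855, 0.0454 without E14.5 replicate 2 and 0.0495 without the filter on low counts). Neurog3, the transcription factor gene of endocrine progenitors, rose 7.94-fold, and Sct, encoding secretin, also rose. Paneth-cell genes had 4 of 17 up and 1 down (adjusted p = 0.643), and tuft-cell genes 4 of 16 up and 5 down (adjusted p = 0.859).

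Of 36 oxidative phosphorylation genes, 32 rose and 0 fell (adjusted p = 3.91e-09, and adjusted p = 0.418 with an estimated correlation), with the succinate dehydrogenase gene Sdhd at 2.36-fold. Fatty acid oxidation genes rose in 21 of 29 and fell in 0 (adjusted p = 7.94e-07, and adjusted p = 0.418 with an estimated correlation), with the coactivator gene Ppargc1b at 5.53-fold. Glycolysis genes rose in 14 of 22 and fell in 3 (adjusted p = 0.00364, and adjusted p = 0.418 with an estimated correlation), with the phosphofructokinase gene Pfkp at 9.25-fold. Cholesterol synthesis genes rose in 10 of 23 and fell in 1 (adjusted p = 0.0162, and adjusted p = 0.656 with an estimated correlation). Ribosome biogenesis genes rose in 9 of 33 and fell in 0 (adjusted p = 0.0328, and adjusted p = 0.768 with an estimated correlation). That call was lost without E12.5 replicate 2 (adjusted p = 0.0564). Proliferation genes had 4 of 36 up and 3 down (adjusted p = 0.856), a balance that turned to 4 up and 6 down with DESeq2, 2 and 4 with relative log scaling and 2 and 3 with upper-quartile scaling. Mki67, a marker of cycling cells, stood at 1015 ± 22.5 against 1327 ± 23.9 CPM (adjusted p = 0.0927). It passed with DESeq2 (adjusted p = 0.0448) and in an edgeR fit of the 6 libraries alone (adjusted p = 0.000412). Of DESeq2's calls, 22.2% were false in simulated counts, but those held far fewer changed genes than were called here.

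Of 27 oncofetal and progenitor genes, 20 fell and 1 rose (adjusted p = 8.46e-07, and adjusted p = 0.0693 with an estimated correlation). Sall4, a transcription factor gene of embryonic progenitors, fell from 94.4 ± 7.30 to 12.4 ± 1.51 CPM, and Prtg, encoding protogenin, fell 21.1-fold. Imprinted genes fell in 17 of 25 and rose in 4 (adjusted p = 9.39e-05, and adjusted p = 0.0693 with an estimated correlation), with Zim1 down 13.4-fold and Nnat down 6.96-fold. Hox genes fell in 11 of 17 and rose in 1 (adjusted p = 0.0255, and adjusted p = 0.504 with an estimated correlation). The list call was lost without E12.5 replicate 3 (adjusted p = 0.0668) or E14.5 replicate 2 (adjusted p = 0.0526). Trithorax and H3K4 methylation genes fell in 13 of 21 and rose in 2 (adjusted p = 0.00495, and adjusted p = 0.434 with an estimated correlation), with the methyltransferase gene Mll1 down 2.00-fold. Polycomb genes had 8 of 34 up and 13 down (adjusted p = 0.212), with Cbx2 down 2.32-fold. Replication-dependent histone genes, near-identical copies counted with uncertainty, fell in 15 of 39 and rose in 2 (adjusted p = 0.0162, and adjusted p = 0.759 with an estimated correlation). That call was lost without E12.5 replicate 3 (adjusted p = 0.0505) or E14.5 replicate 2 (adjusted p = 0.0667). Of 20 Hedgehog and BMP genes 6 rose and 12 fell (adjusted p = 0.173). Of 25 Wnt targets and receptors 7 rose and 11 fell (adjusted p = 0.462), with the repressor gene Tcf7l1 down 3.44-fold. Cdx2, the master regulator gene of intestinal identity, fell from 73.1 ± 9.60 to 56.5 ± 2.15 CPM (adjusted p = 0.0439). That call was lost without any 1 of 5 libraries, at adjusted p = 0.158 and 0.126 without E12.5 replicates 1 and 3, at 0.0633 without the filter on low counts, and at 0.0810, 0.13 and 0.115 without E14.5 replicates 1, 2 and 3.

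Markers of mesenchyme and smooth muscle also differed between the stages, in cells gated on EpCAM. Of 27, 20 rose and 4 fell at E14.5 (adjusted p = 6.42e-06, and adjusted p = 0.382 with an estimated correlation). Col6a1, a collagen gene, rose from 0.361 ± 0.0759 to 11.7 ± 2.14 CPM, and Actg2 rose 22.0-fold. The 4 that fell included the fibronectin gene Fn1, from 1568 ± 93.8 to 285 ± 27.2 CPM, and the vimentin gene Vim, from 160 ± 24.2 to 72.6 ± 0.801 CPM. Endothelial markers had 4 of 11 up and 3 down (adjusted p = 0.531, and 2 up and 3 down with DESeq2), enteric neural markers 5 of 19 up and 3 down (adjusted p = 0.431), immune markers 3 of 19 each way (adjusted p = 0.955) and red-cell markers 3 of 6 up and 1 down (adjusted p = 0.431). Also not called were Notch (10 of 18 up, 4 down, adjusted p = 0.0832), cell-cycle inhibitor (7 of 16 up, 1 down, 0.0835), DNA methylation (2 of 17 up, 4 down, 0.553) and interferon response genes (10 of 39 up, 12 down, 0.779). The same held for markers of pancreas, liver and stomach (3 of 11 up, 4 down, 0.859), immediate-early (7 of 29 up, 3 down, 0.102, and 0.0478 without E12.5 replicate 1), unfolded protein response (7 of 26 up, 1 down, 0.0656, and 0.0378 without E14.5 replicate 3) and sex-chromosome genes (0 of 6 up, 3 down, 0.345). The median, the mean and the test differed in sign for Hedgehog and BMP, intestinal transcription factor, DNA methylation, immune and pancreas, liver and stomach genes.

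Over all genes 3618 rose and 3926 fell, 3458 of them by a log2 change of at least 1, and in a fit of the 6 libraries alone the balance turned to 5167 up and 4872 down. The groups did not overlap for 70.6% of genes, where chance gives 10%. On genes sharing no 50-base stretch with another gene, a set chosen after the data were seen that left 5 to 14 members in these lists, the calls for xenobiotic metabolism, antigen presentation, epithelial defence, ribosome biogenesis, glycolysis and cholesterol synthesis were lost, at adjusted p = 0.296, 0.287, 0.159, 0.536, 0.163 and 0.0657. Adjusted over the list alone, counts up and down were 8 and 12 for Wnt, 11 and 4 for Notch, 8 and 12 for Hedgehog and BMP, 18 and 3 for microvillus, 1 and 21 for oncofetal, 2 and 3 for DNA methylation, 12 and 13 for interferon, 21 and 4 for mesenchymal, 2 and 2 for enteric neural, 5 and 1 for unfolded protein response, 8 and 0 for ribosome biogenesis and 33 and 0 for oxidative phosphorylation genes. For proliferation genes they were 0 and 0 by edgeR, with 10 of 36 at unadjusted p under 0.05, and for the other lists they were the same. Standard errors of the log2 changes of named genes away from the floor ran from 0.09 to 0.66.

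**Figure D3:**
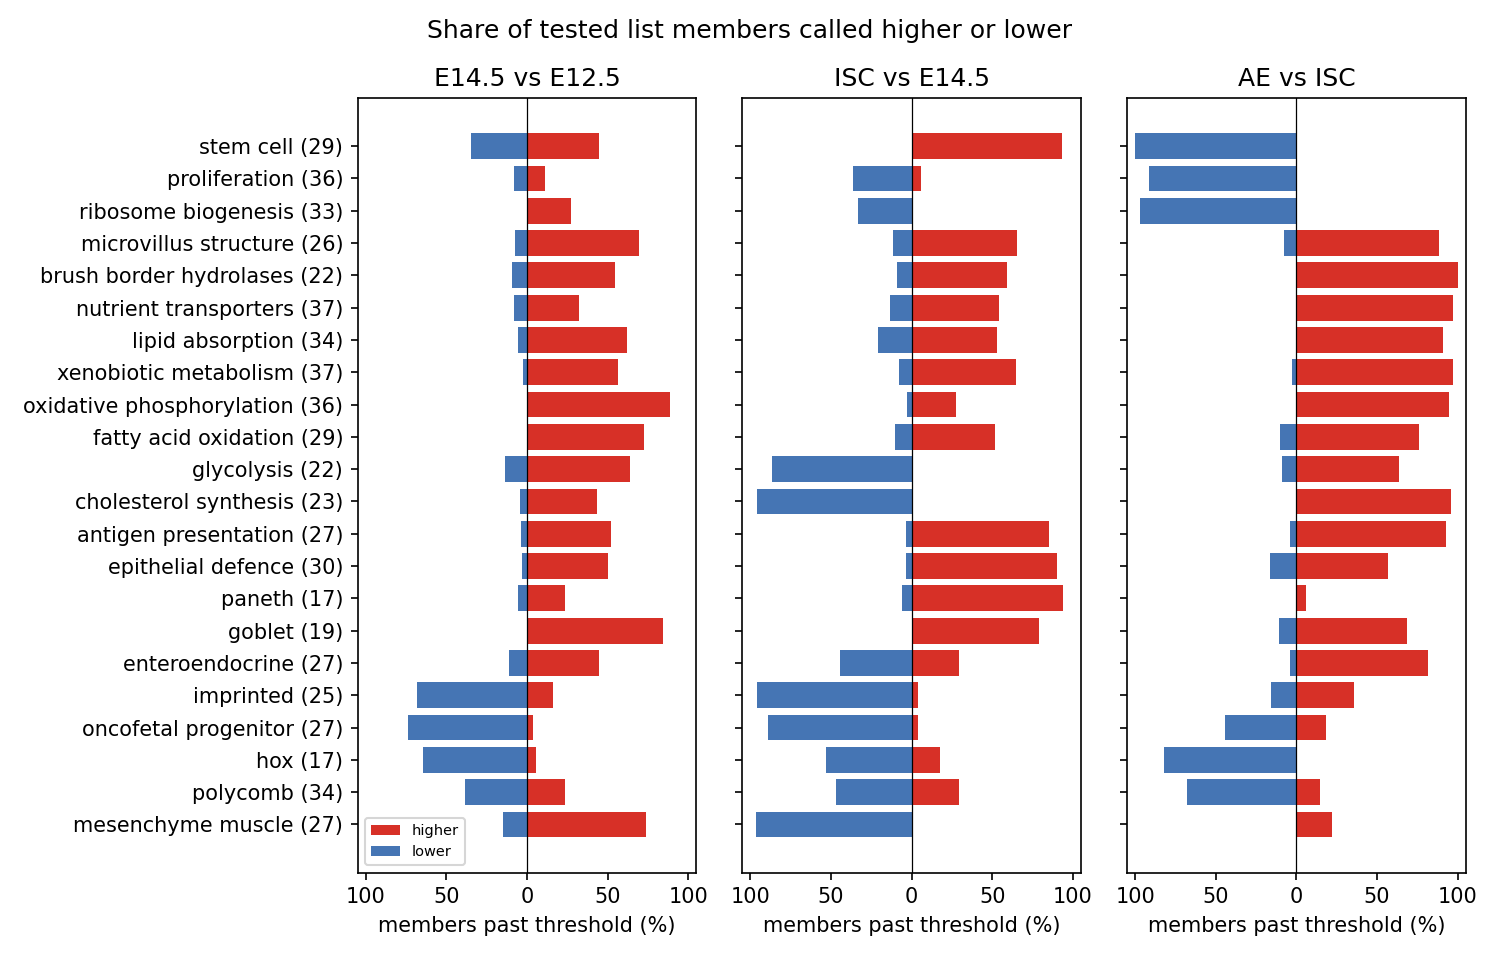
Bars give the percent of tested members of 22 gene lists called higher (right) or lower (left) in each comparison, with the number tested in parentheses. Stem-cell genes are all lower in AE than in ISC, 29 of 29, while 22 of 22 brush-border hydrolases are higher.

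The comparison of ISC with E14.5 asked what sets adult stem cells apart from the embryonic epithelium that precedes them. Stem-cell and epithelial defence genes were higher in ISC, and imprinted, oncofetal, glycolysis and mesenchymal genes were lower, the 6 of 26 list calls that held with an estimated correlation. E14.5 may hold mesenchymal cells carried through its gate, as weighed below. Falls of mesenchymal genes, and of other genes such cells express, cannot be told apart from the absence of those cells in ISC. Olfm4, a marker of adult crypt stem cells, stood at 5743 ± 230 CPM in ISC and at 2.38 ± 0.282 CPM in E14.5, a 2378-fold rise, whereas Lgr5 rose 6.20-fold to 508 ± 39.6 CPM. H19, an imprinted growth-related RNA, fell from 6451 ± 357 to 0.338 ± 0.132 CPM. Vdr, encoding the vitamin D receptor, rose 324.5-fold to 1394 ± 85.8 CPM.

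Of 29 stem-cell genes, 27 rose and 0 fell (adjusted p = 7.07e-16), and the call held at adjusted p = 0.0120 with an estimated correlation. Because the sort took cells with high Lgr5-EGFP, higher Lgr5 and other stem-cell markers in ISC follow at least in part from the gate. Gkn3 rose 122-fold to 21.9 ± 5.28 CPM. Of 25 Wnt targets and receptors, 17 rose and 6 fell (adjusted p = 0.00563, and adjusted p = 0.324 with an estimated correlation). The stem-cell transcription factor gene Ascl2 stood at 114 ± 32.5 against 10.5 ± 0.207 CPM, and Sp5 rose 22.9-fold. Notch genes had 9 of 18 up and 7 down (adjusted p = 0.281), with the target gene Nrarp, uncertain with 77.3% of its sequence shared, up 4.55-fold. Hedgehog and BMP genes had 6 of 20 up and 11 down (adjusted p = 0.120), with Shh down to 0.578 ± 0.201 CPM and Gli3, at 25.3 ± 0.858 CPM in E14.5, at 0 counts in ISC, at least 482-fold lower. Proliferation genes fell in 13 of 36 and rose in 2 (adjusted p = 0.0335, and adjusted p = 0.662 with an estimated correlation), with the ribonucleotide reductase gene Rrm2 down 3.07-fold, while Mki67 rose 2.09-fold to 2118 ± 262 CPM. Ribosome biogenesis genes fell in 11 of 33 and rose in 0 (adjusted p = 0.00738, and adjusted p = 0.613 with an estimated correlation).

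Of 25 imprinted genes, 24 fell and 1 rose (adjusted p = 1.45e-10), and of 27 oncofetal genes, 24 fell and 1 rose (adjusted p = 1.95e-11). Both held with an estimated correlation, each at adjusted p = 0.00526 with an estimated correlation. Meg3, a noncoding RNA that is uncertain without strand because it overlaps others, was at 184 ± 5.04 CPM in E14.5 and had 1 count over the ISC libraries, and Igf2bp1, an oncofetal RNA-binding protein gene at 306 ± 5.59 CPM, had 4. Palm3, Cbln2 and Prrg3, at 64.6 ± 2.01, 55.3 ± 1.33 and 43.5 ± 4.57 CPM in E14.5, had 0 counts in ISC and were at least 1229-, 1052- and 829-fold lower. Hox genes had 3 of 17 up and 9 down (adjusted p = 0.247), and polycomb genes 10 of 34 up and 16 down (adjusted p = 0.300), with the histone-binding gene Rbbp7 down 2.69-fold. DNA methylation genes had 4 of 17 up and 7 down (adjusted p = 0.612), and the de novo methyltransferase gene Dnmt3a fell from 701 ± 21.6 to 143 ± 6.94 CPM. Trithorax genes had 10 of 21 up and 8 down (adjusted p = 0.287), and Mll1 rose 2.53-fold.

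Of 27 antigen presentation genes, 23 rose and 1 fell (adjusted p = 6.86e-08, and adjusted p = 0.324 with an estimated correlation). Cd74, the invariant chain gene of class II presentation, stood at 631 ± 96.1 against 0.422 ± 0.0677 CPM, and H2-Aa went from 4 counts over the E14.5 libraries to 78.6 ± 27.4 CPM. Interferon response genes rose in 32 of 39 and fell in 3 (adjusted p = 1.09e-05, and adjusted p = 0.472 with an estimated correlation), with Ifi47 up 75.8-fold. Immune-cell markers had 7 of 19 up and 2 down (adjusted p = 0.287). Epithelial defence genes rose in 27 of 30 and fell in 1 (adjusted p = 1.64e-08), and the call held at adjusted p = 0.0492 with an estimated correlation. Pigr, which carries antibodies across the epithelium, rose 1007-fold to 4062 ± 1139 CPM, and Reg3g, an antimicrobial lectin gene, went from 4 counts to 48.7 ± 29.4 CPM.

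Transcripts of other crypt and villus cells were present in ISC. Paneth-cell genes rose in 16 of 17 and fell in 1 (adjusted p = 1.05e-05, and adjusted p = 0.363 with an estimated correlation). The lysozyme gene Lyz1 stood at 2848 ± 734 CPM, and Itln1 at 200 ± 83.7 CPM against 1 count over the E14.5 libraries. The defensin-like genes Gm14851 and Gm15284 were at least 11520- and 7799-fold higher against 0 counts. These defensin genes are near-identical copies and their levels are uncertain. Goblet-cell genes rose in 15 of 19 and fell in 0 (adjusted p = 1.83e-05, and adjusted p = 0.300 with an estimated correlation), with the mucin gene Muc2 at 649 ± 99.8 CPM. Tuft-cell genes rose in 12 of 16 and fell in 1 (adjusted p = 0.00111, and adjusted p = 0.119 with an estimated correlation), with the cation channel gene Trpm5 up 8.68-fold. Enteroendocrine genes had 8 of 27 up and 12 down (adjusted p = 0.434), with Sct down 21.4-fold. Immediate-early and stress genes, which can respond to handling, rose in 23 of 29 and fell in 1 (adjusted p = 1.48e-06, and adjusted p = 0.324 with an estimated correlation). The heat shock gene Hspa1a, which shares 66.3% of its sequence with other genes and is uncertain, stood at 161 ± 67.3 against 0.626 ± 0.120 CPM.

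Microvillus genes rose in 17 of 26 and fell in 3 (adjusted p = 0.000366, and adjusted p = 0.363 with an estimated correlation), with Cobl, an actin nucleator gene, up 25.3-fold. Xenobiotic metabolism genes rose in 24 of 37 and fell in 3 (adjusted p = 0.000435, and adjusted p = 0.545 with an estimated correlation), with Cyp2e1 at 58.1 ± 7.83 CPM and at least 2209-fold higher against 0 counts. Brush-border hydrolases rose in 13 of 22 and fell in 2 (adjusted p = 0.0246, and adjusted p = 0.662 with an estimated correlation), with the sucrase-isomaltase gene Sis at 268 ± 126 CPM. Nutrient transporters rose in 20 of 37 and fell in 5 (adjusted p = 0.0493, and adjusted p = 0.671 with an estimated correlation). That call was lost without E14.5 replicate 1 or 2 or ISC replicate 2, at adjusted p = 0.0580, 0.0531 and 0.0744, and at a minimum of 1 CPM, at adjusted p = 0.0660. Lipid absorption genes had 18 of 34 up and 7 down (adjusted p = 0.160), with the sterol exporter gene Abcg8 up 220-fold, or 364-fold without E14.5 replicate 1. Intestinal transcription factor genes rose in 19 of 38 and fell in 6 (adjusted p = 0.00491, and adjusted p = 0.379 with an estimated correlation). Hnf4a rose 1.65-fold, Cdx2 stood at 61.9 ± 12.4 and 56.5 ± 2.15 CPM (adjusted p = 0.443), and Epcam at 1043 ± 49.7 and 854 ± 20.4 CPM (adjusted p = 0.121, and 0.0166 in a fit of the 6 libraries alone).

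Cholesterol synthesis genes fell in 22 of 23 and rose in 0 (adjusted p = 9.07e-10, and adjusted p = 0.227 with an estimated correlation). Glycolysis genes fell in 19 of 22 and rose in 0 (adjusted p = 1.14e-09), and the call held at adjusted p = 0.0492 with an estimated correlation. Slc16a3, a lactate exporter gene, fell 31.9-fold, from 31.8 ± 4.25 to 0.978 ± 0.396 CPM. Fatty acid oxidation genes rose in 15 of 29 and fell in 3 (adjusted p = 0.00597, and adjusted p = 0.541 with an estimated correlation), with Pdk4, which restrains glucose oxidation, up 119.5-fold. Oxidative phosphorylation genes had 10 of 36 up and 1 down (adjusted p = 0.150, and 0.00629 without ISC replicate 3). Unfolded protein response genes had 6 of 26 up and 5 down (adjusted p = 0.890), against 6 up with 9 down under DESeq2 and 8 down under relative log and upper-quartile scaling. Replication-dependent histone genes, uncertain for the same reason as before, rose in 22 of 39 and fell in 0 (adjusted p = 0.000128, and adjusted p = 0.488 with an estimated correlation).

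Mesenchymal markers fell in 26 of 27 and rose in 0 (adjusted p = 3.44e-11), which held at adjusted p = 0.0492 with an estimated correlation, with the collagen gene Col3a1 at 67.6 ± 11 CPM in E14.5 and at 1 count over the ISC libraries. Enteric neural markers fell in 15 of 19 and rose in 2 (adjusted p = 0.000301, and adjusted p = 0.119 with an estimated correlation). Markers of pancreas, liver and stomach fell in 7 of 11 and rose in 0 (adjusted p = 0.0207, and adjusted p = 0.324 with an estimated correlation). The latter call was lost in a fit of the 6 libraries alone (adjusted p = 0.0515). Endothelial markers had 1 of 11 up and 6 down (adjusted p = 0.0657, and 0.00857 without the filter on low counts), called without E14.5 replicate 2 or 3 or ISC replicate 1, at adjusted p = 0.0486, 0.0150 and 0.0365. Red-cell markers had 1 of 6 up and 4 down (adjusted p = 0.126), and cell-cycle inhibitor genes 9 of 16 up and 2 down (adjusted p = 0.0657, and 0.0481 without ISC replicate 3). The median, the mean and the test differed in sign for Notch and unfolded protein response genes. Sex-chromosome genes rose in 5 of 6 and fell in 1 (adjusted p = 0.0461, and adjusted p = 0.300 with an estimated correlation). That call was lost with the replicate number as a block (adjusted p = 0.0584), without E14.5 replicate 1 (0.0561), at a minimum of 1 CPM (0.114) and in a fit of the 6 libraries alone (0.0700). The adults were males and the embryos pooled, so sex cannot be told apart from stage for these genes. The list mixes Y-linked genes with Xist, which stood at 1414 ± 233 unadjusted CPM in E14.5 and 9.22 ± 1.17 in ISC. Over all genes 4627 rose and 4692 fell (4464 and 4399 at a minimum of 1 CPM), 5091 of them by a log2 change of at least 1, and the groups did not overlap for 72% of genes, where chance gives 10%.

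Adjusted over the list alone, counts up and down were 28 and 1 for stem-cell, 19 and 7 for lipid absorption, 20 and 6 for intestinal transcription factor, 13 and 1 for tuft-cell, 1 and 7 for endothelial, 23 and 2 for immediate-early, 0 and 9 for ribosome biogenesis, 9 and 1 for oxidative phosphorylation and 0 and 20 for glycolysis genes, and were the same for the other lists. Standard errors of the log2 changes of named genes away from the floor ran from 0.10 to 1.26. On genes sharing no 50-base stretch, a set chosen after the data were seen that left 6 to 22 members in these lists, the calls for proliferation, hydrolases, transporters, xenobiotic metabolism, intestinal transcription factors, interferon response, pancreas, liver and stomach, ribosome biogenesis and fatty acid oxidation were lost, at adjusted p = 0.345, 0.354, 0.127, 0.283, 0.0991, 0.0730, 0.0800, 0.270 and 0.170.

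**Figure D4:**
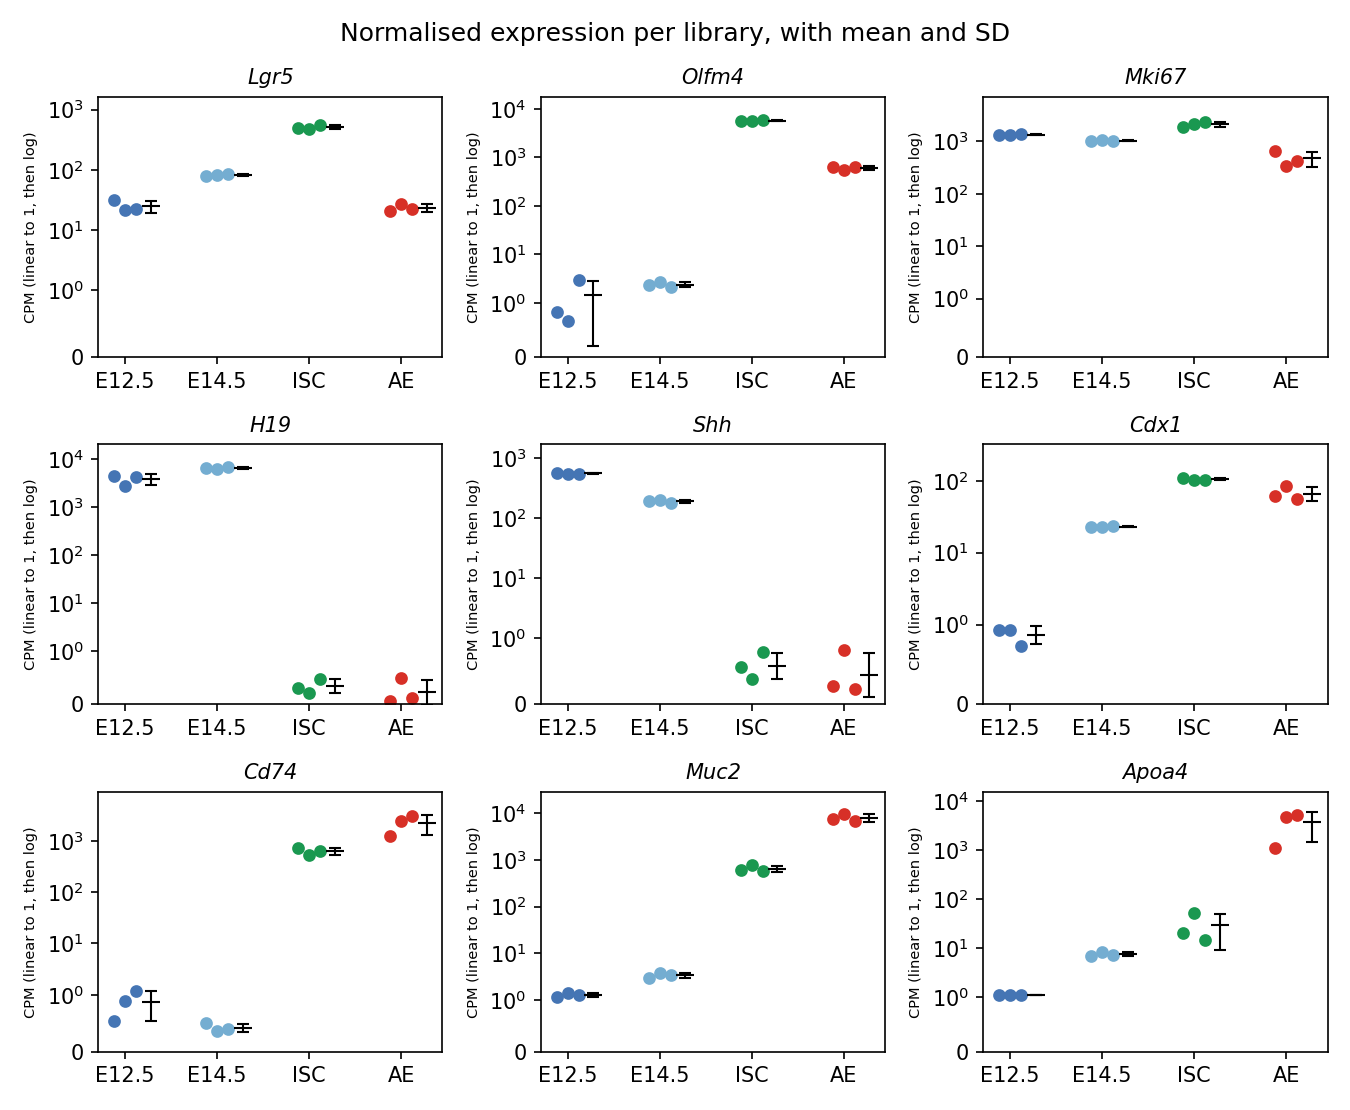
Points are single libraries, and the bars beside them mean and SD of 3, in CPM on an axis linear up to 1 and logarithmic above it, for 9 genes in the 4 groups. Olfm4 lies at 5743 CPM in ISC, 606 in AE and 2.38 in E14.5, and H19 at 6451 CPM in E14.5 and 0.338 in ISC.

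The comparison of AE with ISC asked how expression differed between villus epithelium and the stem cells that renew it. Stem-cell, proliferation and ribosome biogenesis genes were lower in AE, and brush-border hydrolase, nutrient transporter, oxidative phosphorylation, antigen presentation and enteroendocrine genes were higher. Of these list calls only that of stem-cell genes held with an estimated correlation. That estimate came from the spread within groups over all 12 libraries. Among the AE libraries, replicate 1 was the lowest for 22 of 22 hydrolases and the highest for 32 of 36 proliferation genes. Whether that library raised the estimate was not tested, so the losses do not show that these lists did not change. Lgr5 fell 21.8-fold, from 508 ± 39.6 to 23.3 ± 3.20 CPM, and Olfm4 fell 9.48-fold, remaining at 606 ± 58.7 CPM. Akp3 rose from 1.31 ± 0.839 to 1614 ± 705 CPM and Apoa4, uncertain as above, from 29.7 ± 20.4 to 3692 ± 2235 CPM, where the Apoa4 rise of 124-fold was 205-fold without ISC replicate 2. Mki67 fell 4.50-fold and stood at 471 ± 153 CPM in AE.

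Of 29 stem-cell genes, 29 fell (adjusted p = 8.20e-16), and the call held at adjusted p = 0.0309 with an estimated correlation, the only one of 27 list calls in this comparison to do so. As ISC were sorted by high Lgr5-EGFP and the list holds stem-cell markers, Lgr5 among them, this direction was set in advance by the sort. Tnfrsf19, a receptor gene, fell 15.1-fold. Wnt targets and receptors fell in 17 of 25 and rose in 3 (adjusted p = 3.50e-05, and adjusted p = 0.254 with an estimated correlation), with Ascl2 down 14.3-fold. Notch genes fell in 7 of 18 and rose in 1 (adjusted p = 0.0267, and adjusted p = 0.254 with an estimated correlation), with the receptor gene Notch1 down 7.09-fold. The list call was lost without ISC replicate 2 (adjusted p = 0.0597) or AE replicate 3 (adjusted p = 0.0511). Proliferation genes fell in 33 of 36 and rose in 0 (adjusted p = 9.11e-10, and adjusted p = 0.270 with an estimated correlation), with Cenpf, a kinetochore gene, at 94.4 ± 29.0 against 498 ± 131 CPM. Cell-cycle inhibitor genes rose in 9 of 16 and fell in 3 (adjusted p = 0.00723, and adjusted p = 0.254 with an estimated correlation), with Cdkn2b up 36.3-fold. Ribosome biogenesis genes fell in 32 of 33 and rose in 0 (adjusted p = 4.19e-10, and adjusted p = 0.268 with an estimated correlation). Rrp1b stood at 14.6 ± 4.04 against 98.1 ± 15.2 CPM, and Nop56 fell 4.81-fold.

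All 22 brush-border hydrolases rose (adjusted p = 3.12e-11, and adjusted p = 0.254 with an estimated correlation), and Tmprss15 stood at 75.1 ± 47.1 CPM against 1 count over the ISC libraries. Nutrient transporters rose in 36 of 37 and fell in 0 (adjusted p = 1.33e-13, and adjusted p = 0.254 with an estimated correlation). Slc6a19, a neutral amino acid transporter gene, rose 98.8-fold, and the phosphate transporter gene Slc34a2 rose 102-fold, or 156- and 214-fold without ISC replicate 2. Lipid absorption genes rose in 31 of 34 and fell in 0 (adjusted p = 2.65e-12, and adjusted p = 0.254 with an estimated correlation), with Fabp1 up 107-fold. Microvillus genes rose in 23 of 26 and fell in 2 (adjusted p = 1.28e-07, and adjusted p = 0.254 with an estimated correlation), with the keratin gene Krt20 at 1742 ± 728 against 28.7 ± 14.7 CPM. Xenobiotic metabolism genes rose in 36 of 37 and fell in 1 (adjusted p = 1.56e-14, and adjusted p = 0.254 with an estimated correlation). Intestinal transcription factor genes had 17 of 38 up and 12 down (adjusted p = 0.617), against 11 up and 16 down with upper-quartile scaling, among them Creb3l3 up 21.9-fold. Hnf4a rose 1.28-fold to 2157 ± 193 CPM (adjusted p = 0.0204). That call was lost without ISC replicate 1 or 2 (adjusted p = 0.0604 and 0.0923), with upper-quartile scaling (adjusted p = 0.271) in a fit of the 6 libraries alone (adjusted p = 0.100) and on genes sharing no 50-base stretch (adjusted p = 0.0830). Cdx2 stood at 62.3 ± 6.59 and 61.9 ± 12.4 CPM (adjusted p = 0.984), and Epcam rose 1.54-fold.

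Oxidative phosphorylation genes rose in 34 of 36 and fell in 0 (adjusted p = 1.10e-09, and adjusted p = 0.254 with an estimated correlation), with Sdhb up 3.66-fold. Cholesterol synthesis genes rose in 22 of 23 and fell in 0 (adjusted p = 4.94e-07, and adjusted p = 0.254 with an estimated correlation), with Sc5d up 5.15-fold, opposite in sign to their 22 falls between E14.5 and ISC. Glycolysis genes rose in 14 of 22 and fell in 2 (adjusted p = 0.000202, and adjusted p = 0.254 with an estimated correlation), with Pfkp up 14.8-fold to 445 ± 41.4 CPM. Fatty acid oxidation genes rose in 22 of 29 and fell in 3 (adjusted p = 2.20e-05, and adjusted p = 0.287 with an estimated correlation). Unfolded protein response genes rose in 19 of 26 and fell in 1 (adjusted p = 0.000364, and adjusted p = 0.254 with an estimated correlation), with Edem1 up 3.25-fold. Immediate-early and stress genes fell in 20 of 29 and rose in 2 (adjusted p = 0.00142, and adjusted p = 0.407 with an estimated correlation), with Cyr61 at 30.4 ± 18.1 against 722 ± 218 CPM, a 23.3-fold fall that was 36.4-fold without AE replicate 1.

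Antigen presentation genes rose in 25 of 27 and fell in 1 (adjusted p = 1.44e-08, and adjusted p = 0.254 with an estimated correlation). H2-Q1 and H2-Q2, members of a family of near-identical class I genes and uncertain for that reason, rose 74.5- and 17.9-fold. Interferon response genes rose in 33 of 39 and fell in 1 (adjusted p = 4.94e-07, and adjusted p = 0.349 with an estimated correlation), with Ifit1 at 58.4 ± 39.1 against 0.734 ± 0.306 CPM. Epithelial defence genes rose in 17 of 30 and fell in 5 (adjusted p = 0.0114, and adjusted p = 0.270 with an estimated correlation), with the secreted lectin gene Reg1 at 2256 ± 707 against 16.3 ± 7.46 CPM. Chromatin lists fell, polycomb genes in 23 of 34 with 5 up (adjusted p = 0.00100, and adjusted p = 0.254 with an estimated correlation), trithorax genes in 15 of 21 with 1 up (adjusted p = 0.00454, and adjusted p = 0.270 with an estimated correlation) and DNA methylation genes in 11 of 17 with 2 up (adjusted p = 0.00800, and adjusted p = 0.254 with an estimated correlation). Cbx6 fell 5.29-fold and Tet1, encoding a methylcytosine oxidase, fell 7.82-fold. Hox genes fell in 14 of 17 and rose in 0 (adjusted p = 0.00453, and adjusted p = 0.254 with an estimated correlation), and replication-dependent histone genes, uncertain as before, fell in 35 of 39 and rose in 1 (adjusted p = 6.88e-06, and adjusted p = 0.349 with an estimated correlation). Imprinted genes had 9 of 25 up and 4 down (adjusted p = 0.799), with Peg3 up 6.92-fold, and oncofetal genes 5 of 27 up and 12 down (adjusted p = 0.163).

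The villus gate also held transcripts of secretory cells. Goblet-cell genes rose in 13 of 19 and fell in 2 (adjusted p = 0.00142, and adjusted p = 0.287 with an estimated correlation). Fcgbp stood at 10260 ± 2918 CPM, Muc2 at 7967 ± 1579 CPM and Zg16 at 3319 ± 1573 CPM. Enteroendocrine genes rose in 22 of 27 and fell in 1 (adjusted p = 2.08e-07, and adjusted p = 0.254 with an estimated correlation), with the hormone gene Gip at 366 ± 217 against 1.94 ± 0.579 CPM. Paneth-cell genes had 1 of 17 up and 0 down (adjusted p = 0.442), with Lyz1 at 3772 ± 2142 CPM in AE. Tuft-cell genes had 7 of 16 up and 1 down (adjusted p = 0.211), immune markers 8 of 19 up and 1 down (adjusted p = 0.165) and mesenchymal markers 6 of 27 up and 0 down (adjusted p = 0.290). Hedgehog and BMP genes had 8 of 20 up and 4 down (adjusted p = 0.638, and 0.0287 on genes sharing no 50-base stretch), endothelial markers 1 of 11 each way (0.558) and enteric neural markers 4 of 19 up and 2 down (0.466). Red-cell markers had 0 of 6 up and 1 down (0.636), markers of pancreas, liver and stomach 3 of 11 each way (0.957) and sex-chromosome genes 0 of 6 up and 3 down (0.360). The median, the mean and the test differed in sign for imprinted and for pancreas, liver and stomach genes.

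Over all genes 5002 rose and 5395 fell, 6247 of them by a log2 change of at least 1, and the groups did not overlap for 66.3% of genes, where chance gives 10%. AE replicate 1 stood apart from AE replicates 2 and 3. It was the highest of the 3 for 32 of 36 proliferation, 31 of 33 ribosome biogenesis and 16 of 17 Paneth-cell genes, and the lowest for 22 of 22 hydrolases, 32 of 37 transporters and 36 of 39 interferon response genes. Without it 10546 genes passed the threshold, against 10397 with it. The median log2 change of all genes was -0.05 with the scaling used here and -0.25 with upper-quartile scaling, which gave 4247 calls up and 6359 down. The balance turned to 5348 up and 5046 down with relative log scaling, 5412 and 5101 with DESeq2 and 5094 and 5003 without AE replicate 3. Adjusted over the list alone, counts up and down were 3 and 19 for Wnt, 32 and 0 for lipid absorption, 3 and 0 for mesenchymal, 4 and 1 for enteric neural, 2 and 3 for pancreas, liver and stomach, 21 and 2 for unfolded protein response, 0 and 33 for ribosome biogenesis, 1 and 36 for histone and 0 and 2 for sex-chromosome genes. For Paneth-cell genes they were 0 and 0 by edgeR, with 1 of 17 at unadjusted p under 0.05, and for the other lists they were the same. Standard errors of the log2 changes of named genes away from the floor ran from 0.09 to 1.31. On genes sharing no 50-base stretch, chosen after the data were seen and leaving 5 to 11 members in these lists, the calls for Notch, cell-cycle inhibitors, trithorax, DNA methylation and glycolysis were lost, at adjusted p = 0.0951, 0.443, 0.0951, 0.858 and 0.361.

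The last comparison asked whether the embryonic step and adult differentiation moved the same genes. Across 15342 genes, which are not independent replicates, the log2 changes of E14.5 against E12.5 and of AE against ISC, which share no library, had a Pearson correlation of 0.202 and a Spearman correlation of 0.252. Of the 3618 genes that rose in the embryo and the 5002 that rose in the adult, 1876 rose in both, where independent lists of those sizes give 1179.6. Of the 3926 and 5395 that fell, 1845 fell in both, against 1380.6. Only 795 rose and then fell, against 1272.3, and 714 fell and then rose, against 1280. The lists called higher in both were microvillus, lipid absorption, xenobiotic metabolism, antigen presentation, epithelial defence, goblet-cell, oxidative phosphorylation, glycolysis, fatty acid oxidation and cholesterol synthesis genes. Hox, trithorax and histone genes were called lower in both, and ribosome biogenesis genes higher in the embryo and lower in the adult. All of these calls were lost in both comparisons with an estimated correlation, at adjusted p = 0.382 to 0.768 with an estimated correlation in the embryo and 0.254 to 0.349 in the adult. Between these steps, in ISC against E14.5, glycolysis genes fell in 19 of 22 and cholesterol synthesis genes in 22 of 23. Their rises in AE therefore started from levels below those of E14.5. The embryonic and adult contrasts both cross the split in how multiply aligned reads were listed, in the same direction, and a batch that follows that split cannot be told apart from the groups. The correlation was 0.192 in a fit of genes sharing no 50-base stretch, chosen after the data were seen.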

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

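Among the tests weighed here, the one of swapped stage titles had its criterion set only after the result was seen. The counting summaries outside the gene counts held reads in every library. Reads listed as not uniquely aligned averaged 1.988 ± 0.369 in E12.5 and 2.141 ± 0.212 in ISC, in units of 1000000 per library (SD, n = 3), and were listed at 0 in the 6 E14.5 and AE libraries. Reads listed outside annotated genes averaged 52.737% ± 5.99 of all reads listed in E12.5, 39.983% ± 0.640 in E14.5, 46.65% ± 0.574 in ISC and 36.03% ± 2.80 in AE, so the groups that list reads with several alignments also list more reads outside genes. These values lie outside the main measurement, and no control samples exist to set them against.

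Changes in the embryonic step and in adult differentiation were weakly correlated, at 0.202 across genes. Both steps run from a group that lists multiply aligned reads to one that lists none. Reads counted for several similar genes could give such a correlation, which would then weaken on genes with no shared sequence. Over the 5995 genes with no 50-base stretch in another gene's transcripts it was 0.195 (95% bootstrap interval over genes 0.161 to 0.228), above the bound of 0.15 set before the result was seen, which argues against shared reads as the whole cause. Swapped embryonic titles would turn the sign of the first step, but 87.5% of the called enterocyte-list members (63 of 72, exact interval 77.6 to 94.1) were higher in the libraries titled E14.5, which argues against the age labels as far as those lists are known to rise with age. The interval treats genes as independent and is too narrow, since the estimated correlations within these lists ran from 0.282 to 0.825. It measures no spread between animals. Other differences between libraries that follow the same split cannot be told apart from the groups, and a shared biological program of maturation remains open and untested.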

How the results depend on the processing

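The run on genes sharing no 50-base stretch and the run without Rn45s and Lars2 were chosen after seeing the data. The counts of genes past the threshold stayed within 1.5 times under every alternative except the first of these, which tests only 6030 genes by construction and called 3096, 3767 and 3973 for E14.5 against E12.5, ISC against E14.5 and AE against ISC. In fits of the 6 compared libraries alone, 10039 of 14836, 9799 of 14420 and 8864 of 13330 genes passed, in the same order. The main fit gave 7544, 9319 and 10397, so the ranking of the comparisons by count turned. It shares 1 spread per gene over all groups. In highly counted genes, replicates differed by a log2 SD of 0.046 (E14.5 replicates 1 and 2) to 0.36 (AE replicates 1 and 2). Leaving out each library gave 6151 to 6631, 8339 to 9004 and 9869 to 10546 genes, and 14206 to 14628 genes differing between any groups. The correlation between the embryonic and adult changes stayed above 0, at 0.14 without a filter on low counts, 0.216 at 1 CPM, 0.192 with limma-voom, 0.192 on genes sharing no stretch and 0.183 to 0.213 with 1 library left out; except for the smaller gene set, the cause was not tested. Replicate numbers were not taken as pairs, since the labels do not say that a number marks 1 animal or day. In deviations from group means, same-numbered ISC and AE libraries correlated at 0.033, 0.175 and 0.086. Their mean was 0.098, against -0.048 for differently numbered ones. The same-number means of the other group pairs ran from -0.108 to 0.037. Each E12.5 library correlated best with the ISC library of its own number, and 2 ISC libraries did so with AE, a hint from the data only. These values do not decide whether the libraries were paired. With the replicate block 7258, 9103 and 10229 genes were called, and of the list calls it ended that for sex-chromosome genes in ISC against E14.5 (adjusted p = 0.0584). Of 17, 26 and 27 list calls, 17, 20 and 26 were lost with an estimated correlation and 3, 2 and 1 with some library left out. On genes sharing no stretch 15, 22 and 25 of them could be tested, and 6, 9 and 5 of these were lost. Not tested there were the histone calls of all 3 comparisons, the Hox calls of the embryo and of AE against ISC, and the Paneth, tuft and sex-chromosome calls of ISC against E14.5. In ISC against E14.5, 2 were lost at 1 CPM (nutrient transporters, 0.0660, and sex chromosomes, 0.114) and 2 in the 6 libraries alone (pancreas, liver and stomach, 0.0515, and sex chromosomes, 0.0700). Calls were also gained. In E14.5 against E12.5 these were 6 without filter (cell-cycle inhibitors 0.0498, hydrolases 0.0433, transporters 0.0404, enteroendocrine 0.0495, immediate-early 0.0498, unfolded protein response 0.0185) and 3 in the 6 libraries alone (hydrolases 0.0369, transporters 0.0411, unfolded protein response 0.0143). With 1 library left out they were enteroendocrine (0.0454 without E14.5 replicate 2), immediate-early (0.0478 without E12.5 replicate 1) and unfolded protein response (0.0378 without E14.5 replicate 3). In ISC against E14.5 the endothelial list was gained without filter (0.00857) and without E14.5 replicate 2 or 3 or ISC replicate 1 (0.0486, 0.0150 and 0.0365), and without ISC replicate 3 cell-cycle inhibitors (0.0481) and oxidative phosphorylation (0.00629) were. In AE against ISC, Hedgehog and BMP genes were gained on genes sharing no stretch (0.0287). No called list with a value reversed under the alternatives run for lists, and the cause of these changes was not tested. The lists that reversed were past the threshold on neither side. In E14.5 against E12.5 these were, by adjusted p, Hedgehog and BMP (0.5053 on genes sharing no stretch), proliferation (0.5697 there), DNA methylation (0.4288 there), tuft (0.981 without filter), immune cells (0.8773 without filter, 0.9813 at 1 CPM, 0.7368 in the 6 libraries alone) and pancreas, liver and stomach (0.4966 without filter, 0.9687 with the block, 0.7127 on genes sharing no stretch). With 1 library left out the range was 0.8098 to 0.993 for proliferation and 0.7417 to 0.993 for tuft, both reversed without E12.5 replicate 3 (0.993). It was 0.8875 to 0.9638 for immune cells, reversed without E12.5 replicate 1 (0.9302), and 0.596 to 0.8807 for pancreas, liver and stomach, reversed without E12.5 replicate 1 (0.8582) or E14.5 replicate 2 (0.6937). In ISC against E14.5 they were trithorax (0.8286) and DNA methylation (0.3543) on genes sharing no stretch, and immune cells (0.7847) and unfolded protein response (0.6689) in the 6 libraries alone. In AE against ISC they were pancreas, liver and stomach (0.8159 with upper-quartile scaling, 0.8083 without filter, 0.8566 to 0.9988 with 1 library left out, reversed at 0.9988 without ISC replicate 2) and Paneth (0.1784 to 0.7243 with 1 library left out, reversed without ISC replicate 3 at 0.7243 or AE replicate 1 at 0.7173). The log2 change of Cdx2, not called in either adult comparison, ran from -0.068 to 0.261 in ISC against E14.5 and from -0.126 to 0.206 in AE against ISC with 1 library left out. It turned negative without ISC replicate 3 (-0.068) in the first, and without ISC replicates 1 (-0.018) or 2 (-0.126) or AE replicate 3 (-0.029) in the second, where it also was -0.192 with upper-quartile scaling, -0.009 without filter and -0.081 on genes sharing no stretch; the cause was not tested. The list tests were not run with DESeq2, which entered only the counts of list members, nor with limma-voom, since they already use voom values. Depth limits genes near the floor, whose changes are given as bounds or counts.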

Other observations

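The tests of mesenchymal cells in E14.5 and of crypt cells in AE replicate 1 were chosen only after the results were seen, and the splits of the libraries were fixed before. The genes in this paragraph were chosen after their values were seen. Genes of regional or cell identity varied between libraries of a group. Fabp6, an ileal bile acid-binding protein gene, stood at 116, 494.5 and 77.8 CPM in AE replicates 1, 2 and 3, and Slc10a2, the ileal bile acid transporter gene, at 7.96, 33.0 and 4.80 CPM, while Ada, an adenosine deaminase gene high in duodenal villi, stood at 233, 466 and 1016 CPM. Ctrb1, a pancreatic gene, stood at 49.9, 32.2 and 128 CPM in the E14.5 libraries. Xist, which silences an X chromosome in females and cannot be told from its antisense partner Tsix without strand, stood at 1416 ± 620 unadjusted CPM in E12.5 (SD, n = 3), 1414 ± 233 in E14.5, 9.22 ± 1.17 in ISC and 0.556 ± 0.336 in AE, the adult animals being males and the embryos pooled. Hspa1a, uncertain through shared sequence, stood at 232, 152 and 98.6 CPM in ISC and at 17.7, 163 and 1.14 CPM in AE. Rn45s, which holds ribosomal RNA sequence, took 18233 ± 4715 unadjusted CPM in E12.5, 18742 ± 4438 in E14.5, 35782 ± 13865 in ISC and 31945 ± 11440 in AE.

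Mesenchymal genes rose in E14.5, at 67.6 CPM for Col3a1, 65.7 for Acta2 and 61.5 for Myh11, while Fn1 fell to 285 CPM and Vim to 72.6 CPM. Of the 27 list members tested, 17 averaged at least 1 CPM in E12.5, 25 in E14.5 and 4 in each adult group, and 1 is also in another list. A candidate source is mesenchymal or smooth-muscle cells carried through the EpCAM gate, which would remove them if it worked fully, and their genes would then move together between E14.5 libraries. Over the 19 members that rose with at least 100 counts, the median log2 ratio of replicate 3 to replicates 1 and 2 was -0.393, with 16 lower in replicate 3 than in both others, against -0.096 to 0.079 in 10000 random sets matched on expression, in line with a shared source whose share varied. Expression by the epithelial cells themselves, moving together for another reason, and the stage difference remain open, and Fn1 and Vim fell rather than rose.

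AE replicate 1 had higher Paneth-cell, proliferation, ribosome biogenesis and cholesterol synthesis genes than the other AE libraries, with median log2 ratios of 0.92, 0.79, 0.64 and 0.58. Hydrolase, transporter and interferon genes were lower, at -1.30, -1.15 and -0.83. Lgr5-high stem cells could bring this, but at the 28.3% share that the proliferation genes need, the stem-cell list rose by only 10.3% of the rise required (95% bootstrap interval 3.5 to 17), with Lgr5 itself at 20.6, 26.9 and 22.5 CPM in the 3 libraries, which argues against them. Other cycling crypt cells would raise proliferation genes without most stem-cell genes. Of stem-cell genes, 65.5% were highest in replicate 1 (19 of 29), over the bound of 50, but the exact interval of 45.7 to 82.1 holds 50, a condition on spread added after the value was seen, so this stays open. The Paneth-cell rise entered neither test. A different depth of villus collection and the animal itself, 1 gut per library, were not tested.

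The 3 comparisons of 3 against 3 libraries have 10 splits each, too few for a share under 0.05. In fits of the 6 libraries alone, 1 of 10 splits, the real one, gave as many genes, with 10039 for E14.5 against E12.5, 9799 for ISC against E14.5 and 8864 for AE against ISC, and a highest other of 0 by edgeR in each. At unadjusted p under 0.05 the real splits gave 10447, 10162 and 9253 genes and the others at most 83, 139 and 143. Each other split puts both populations on each side, so their difference enters the spread and these counts are no chance baseline. DESeq2 was not run on the splits. For genes differing between any of the 4 groups, 1 of 100 drawn splits, the real one, reached 14318, and the highest other gave 10010. The drawn splits also mix populations, so the real one was bound to lead and no conclusion on chance is drawn. A batch that follows the groups would lead in the same way.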
